A study of Mus musculus with 4 samples.

How the data were processed

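Single-cell RNA was measured with 10x Genomics droplet libraries in mouse embryoid bodies, aggregates of differentiating embryonic stem cells, at day 9. The 4 libraries were 2 from control embryonic stem cells and 2 from embryonic stem cells pulsed with DUX, and the series design describes the 2 libraries of a group as biological replicates. The deposited table held whole-number counts of unique molecular identifiers (UMIs) per gene and cell, with no normalization, and all 4 libraries stood in it as columns. Cell Ranger 2.2.0, STAR and the mouse genome build mm10 were named in the submitters' processing notes, with no role given for each. A filter on cells was not stated in the sources used here. Every cell of the deposited table had at least 501 detected genes and at most 19.98% mitochondrial counts. The group of a cell was read from the start of its column name and its replicate from the number at its end, as in the sample titles. The table held 20284 genes and 10090 cells. Gene positions came from GENCODE vM21, an annotation of the mm10 sequence, by gene symbol: 20034 symbols matched, 250 did not, and 149 names had been made unique in the table. Symbols with 2 or more genes behind them, near-identical paralogs and overlapping genes cannot be separated further in such counts.

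Cells with at least 500 detected genes and at most 10% mitochondrial counts were kept, which left 8876 cells. Doublets were kept in the main results. Scrublet called 27 doublets (0.3% of kept cells) against an expected rate of 5% set for it. Whether its threshold worked was not tested. The 395 kept cells among the top 5% of its scores in each library were therefore removed as an alternative chosen after seeing the data. Median depth of kept cells lay between 27260 and 30402.5 UMIs per library. The tests, the gene lists, the cell type markers and the rule for naming genes were chosen before the data were examined.

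For the whole culture, counts were summed over the kept cells of a library and tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization), DUX-pulsed against control. Genes with at least 10 counts in at least 2 libraries and at least 40 counts in all were tested. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Values per gene are CPM over TMM-scaled library sizes. The rule named the 12 largest rises and the 12 largest falls by log2 fold change among genes past the threshold with a mean of at least 20.0 CPM in the higher group and both DUX-pulsed libraries beyond both control libraries, and the 2 members of each gene list with the smallest p. Mitochondrial and ribosomal protein genes and predicted genes named Gm plus a number or ending in Rik were left out of the naming, though not out of the tests. They made up 35 of the 884 rises and 25 of the 863 falls that met the rule. Dux, Duxf3, Zscan4c and Zscan4d, also on the list of genes to name, are absent from the deposited table and were not analysed here.

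The 29 fixed lists held 17 sets of cell type markers (pluripotency, primed epiblast, primitive streak and nascent mesoderm, definitive endoderm and gut, visceral and primitive endoderm, parietal endoderm, trophoblast, cardiomyocyte, mesenchyme and fibroblast, endothelium, erythroid, myeloid and megakaryocyte, neural progenitor, neuron, neural crest and glia, surface epithelium, primordial germ cell) and 12 other groups (2-cell stage and DUX targets, p53 targets, hypoxia and glycolysis, cell cycle G2 and M, cell cycle S, dissociation and immediate early response, imprinted genes, anterior and posterior Hox genes, WNT, BMP, Nodal and FGF feedback targets, extracellular matrix, interferon and innate immunity). Each was tested with camera in limma 3.58.1 on log CPM with a preset correlation of 0.01 between genes, adjusted over the 29 lists. A correlation estimated per list and fry were the alternatives. Lists share members, so their tests are not independent.

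Cells were clustered together over the 4 libraries with scanpy 1.11.5 and igraph 0.11.9 (10000 counts per cell, log1p, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1) with no batch correction. A cluster took the name of a marker list only if at least 4 of its top 30 genes by fold belonged to the list, at least 3 of its markers and at least 50% of them were raised, and no other list had more members among its top 10 genes. These thresholds on naming were set after the data were seen. A cluster whose median UMI count was more than 3 times below that of its libraries with no such marker in its top 10 genes stayed unnamed. Of 21 clusters, 11 were named and formed 8 classes. Cells per class were tested with edgeR's quasi-likelihood test without an abundance trend, with the kept cells as library size and adjustment over 10 classes (the 8 named, the unnamed and the unnamed of low depth). Shares are also given for a clustering without the genes called in the whole culture. An exact permutation test of a share in 2 against 2 libraries cannot go below a two-sided p of 0.333. Intervals around a share in 1 library (Wilson, 95%) and a floor of 3 counts cover counting error only.

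Counts were summed per library in each class with at least 20 cells in every library (cardiomyocyte-like and mesenchyme- and fibroblast-like) and tested in 1 fit per class with the same gene filter; the 5 largest rises and the 5 largest falls were named by the same rule. Not every gene that these rules named is given in the report. The class-by-group term was tested with edgeR over the 8 sums of these classes, with a term per library. Log2 fold changes within the same classes were then summarised in 10 Mb bins along the chromosomes, a step chosen after seeing the data. A bin with at least 10 genes counted as shifted when its median moved by at least 0.35 (log2) the same way in both classes, and gene positions were shuffled 1000 times.

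For genes, simulated counts had the real library sizes and, except for the class-by-group term, the real spread. Changes were planted only in genes with counts well above the filter. The rates of calls therefore do not cover genes of low counts. The whole-culture test called 47% of genes changed 2-fold and 99% of genes changed 4-fold among 15984 genes, with 20 false calls. The within-class tests called 67% and 100% in the cardiomyocyte-like class (11236 genes, 17 false calls) and 60% and 99% in the mesenchyme-like class (11964 genes, 6 false calls). The class-by-group term was simulated with the same fixed spread for every gene and no library effect shared by the classes. It called 72% of 4-fold differences among 12777 genes, with 0 false calls. These values do not give its error rate in the real data. The share test called 30.3% of 4-fold changes over 10 classes, and 2.3% of classes kept at their share. For the bins, the real fold changes were shuffled over the genes and those of 1 whole chromosome raised by 0.585 (log2). Of the bins of that chromosome 97.5% were found, with a mean of 0.09 other bins.

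Alternatives set beforehand were size factors of DESeq2 in edgeR, DESeq2 1.42.0, no filter and a filter of 50 counts on genes, the replicate number as a block, each library left out in turn, all deposited cells, cells with at least 1000 genes and at most 5% mitochondrial counts, removal of Scrublet calls, cells thinned to 5000 UMIs, Leiden resolutions of 0.5 and 2, 30 neighbours, clustering without called genes, TMM on the class counts, and shares without the class of the largest change. Cells under 5000 UMIs removed, the top 5% of Scrublet scores removed and all fits without genes of the shifted regions and chromosome Y were added after seeing the data.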

Results

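DUX is a transcription factor of the 2-cell mouse embryo whose expression moves embryonic stem cells toward a state resembling that stage. The series asked what cells form in embryoid bodies when the stem cells had received a pulse of DUX. Single-cell UMI counts were measured at day 9 in 2 control and 2 DUX-pulsed libraries. Control replicates 1 and 2 kept 2824 and 2636 cells with 96344329 and 78167098 UMIs. DUX-pulsed replicates 1 and 2 kept 2063 and 1353 cells with 65062824 and 36462169 UMIs. Kept cells had median mitochondrial shares of 6.22% and 6.42% in the controls and 4.01% and 4.54% in the DUX-pulsed libraries. Cells under 5000 UMIs made up 14.1% and 17.9% of control cells and 7.8% and 21.8% of DUX-pulsed cells.

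The first comparison asked which cell types the 2 kinds of embryoid body contained. Cardiomyocyte-like cells made up 20.7% ± 0.567 (SD, n = 2) of DUX-pulsed cells and 4.54% ± 0.841 of control cells. Mesenchyme- and fibroblast-like cells made up 22.9% ± 1.75 against 5.84% ± 1.76, and erythroid-like cells 2.74% ± 0.101 against 0.849% ± 0.249. Visceral and primitive endoderm-like cells, of the type that forms the yolk sac epithelium, went the other way, from 7.18% ± 1.41 in controls to 0.184% ± 0.054, or 3 cells in each DUX-pulsed library. A trophoblast-like cluster held 40 and 16 cells in the DUX-pulsed libraries against 1 and 0 in the controls. Over the pooled groups that was a ratio of 89.5, with an exact counting interval of 15.4 to 3597.7. That interval treats cells as independent and leaves out the spread between libraries.

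With edgeR, the shares rose for the cardiomyocyte-like (log2 fold change 2.18, adjusted p = 0.0102), mesenchyme-like (1.97, adjusted p = 0.0186) and erythroid-like classes (1.68, adjusted p = 0.0215). The trophoblast-like share rose by 6.05 on the log2 scale (SE 0.87, adjusted p = 0.0102). The visceral endoderm-like share fell by 5.28 on the log2 scale (adjusted p = 0.00454). That fall is of the named cluster 10 alone: together with the unnamed cluster 13, which had 4 markers of the same list among its top 30 genes, it held 8.32% ± 1.26 of control and 7.26% ± 0.56 of DUX-pulsed cells, a sum made after the data were seen and not tested. The same list also ranked first for the unnamed clusters 1, 3 and 12, with 2, 0 and 1 of its markers among their top 30 genes. These clusters held larger shares of control than of DUX-pulsed cells and are not in that sum. Endothelium-like cells, at 3.13% ± 0.24 against 0.899% ± 0.681, and myeloid- and megakaryocyte-like cells, at 3.78% ± 1.58 against 0.826% ± 0.685, did not pass (adjusted p = 0.0771 for both). Parietal endoderm-like cells did not pass either (adjusted p = 0.135), with 12.07% of cells in DUX-pulsed replicate 1 and 1.996% in replicate 2. When cells were clustered without the genes called in the whole culture, the same 5 named classes passed, with visceral endoderm-like cells at 13.5% ± 4.18 in controls and 1.18% ± 1.14 in DUX-pulsed libraries (adjusted p = 0.0271). In that clustering cardiomyocyte-like cells made up 19.6% ± 0.572 against 4.08% ± 0.993, mesenchyme-like cells 24.2% ± 1.38 against 6.7% ± 1.64, and erythroid-like cells 2.76% ± 0.067 against 0.794% ± 0.272.

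Shares are relative, so a fall in 1 class raises the others. With TMM on the class counts the cardiomyocyte-like, mesenchyme-like and erythroid-like rises shrank to 0.85, 0.64 and 0.35 and were lost (adjusted p = 0.493, 0.531 and 0.675). The visceral endoderm-like fall passed in each alternative in which that class was named (adjusted p from 3.03e-05 to 0.0271). Leaving out 1 DUX-pulsed library, replicate 1 or replicate 2, left 2 and 3 named classes past the threshold. It ended the calls of the cardiomyocyte-like (adjusted p = 0.131 and 0.0863), mesenchyme-like (0.132 and 0.116) and erythroid-like shares (0.172 and 0.152), at nearly unchanged log2 values from 1.65 to 2.21. Over all alternatives those adjusted p ran from 0.000522 to 0.493, from 0.00074 to 0.531 and from 0.00402 to 0.675. Endothelium-like cells passed without control replicate 1 (adjusted p = 0.0185) or control replicate 2 (0.0466), with a range of 0.00235 to 0.675. Myeloid-like cells passed without control replicate 1 (0.0348; range 0.00074 to 0.531) and parietal endoderm-like cells without DUX-pulsed replicate 2 (0.0174; range 0.000522 to 0.483). The filter of at least 1000 genes and at most 5% mitochondrial counts kept 644 of 2824 and 523 of 2636 control cells. It kept 1320 of 2063 and 694 of 1353 DUX-pulsed cells, so it removed a larger part of the controls. In the cells it kept only the visceral endoderm-like fall passed. There the trophoblast-like share had an adjusted p of 0.0953, with a range of 0.000111 to 0.0953.

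**Figure D1:**
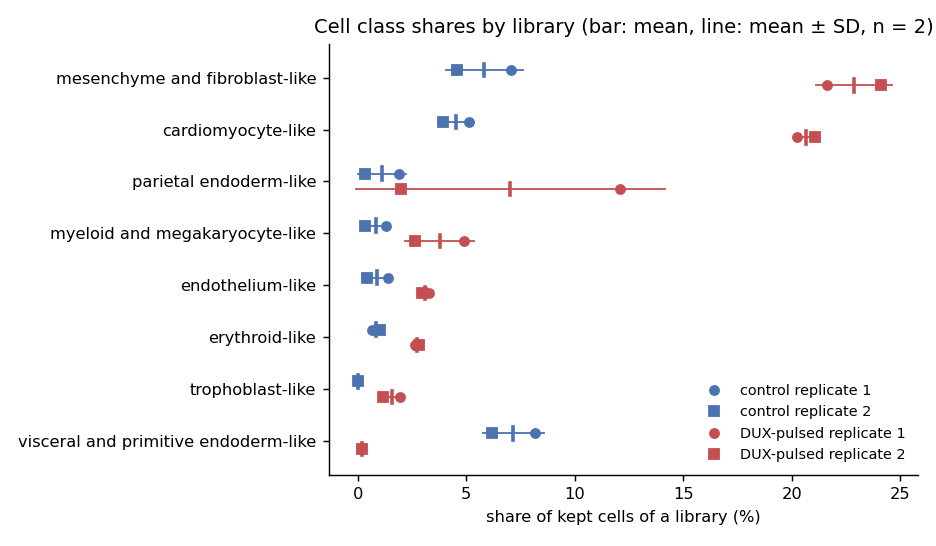
Share of kept cells (%) in each of the 8 named classes. Circles and squares are replicates 1 and 2, blue for control and red for DUX-pulsed, with the mean (bar) and mean ± SD (line, n = 2). Cardiomyocyte-like and mesenchyme-like shares lie at 20.262% or more in both DUX-pulsed libraries and at 7.082% or less in both controls.

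Unnamed clusters held 64.8% ± 3.42 of control and 27.5% ± 0.528 of DUX-pulsed cells, besides 13.9% ± 2.85 and 10.6% ± 7.54 in clusters of low depth. The share of the unnamed fell by 1.24 on the log2 scale (adjusted p = 0.0215), which did not pass in the clustering without called genes (log2 -1.09, adjusted p = 0.0896). Its values under the other alternatives are not given here, and low-depth clusters did not pass (adjusted p = 0.575). The rule that left them unnamed was set after the data were seen. The largest, cluster 1, led by Ly6h, Rarres1 and Flt1, held 23.86% ± 1.94 of control and 0.96% ± 0.62 of DUX-pulsed cells. Cluster 5, led by Trh, Prss12 and Spink1, held 9.8% ± 0.22 against 0.18% ± 0.18, and cluster 8, led by Dnmt3b and Trh, held 9.37% ± 1.77 against 0.18% ± 0.05. In the other direction, cluster 7, led by Ghrl, Afp and Pyy, held 14.1% ± 0.87 of DUX-pulsed and 0.78% ± 0.15 of control cells. Cluster 13, led by the liver-type secretory genes Itih2, Ambp and Vtn, held 7.08% ± 0.61 against 1.14% ± 0.16. Its best list was visceral and primitive endoderm, but fewer than 50% of those markers were raised in it, so it took no name. No test was run on single unnamed clusters.

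The second comparison asked which genes differed when all kept cells of a library were summed. Genes on the myeloid, mesenchyme and cardiomyocyte lists were among the largest rises. The myeloid genes C1qb, a complement subunit, Tyrobp and Fcer1g, signalling adaptors, and Cd52 and Laptm5, leukocyte membrane proteins, stood at means of 20.3 to 61.6 CPM in DUX-pulsed and 0.0304 to 3.3 CPM in control libraries. Tyrobp, on chromosome 7 (30413760 to 30417585, mm10), reached 44.2 ± 22.4 CPM (SD, n = 2) against 0.211 ± 0.281, a log2 fold change of 7.64 (SE 0.89, adjusted p = 0.00376). C1qb, on chromosome 4 (136880129 to 136886187), reached 36.9 ± 21.8 against 0.0304 ± 0.043 CPM, with no UMI in control replicate 1 (log2 10.26, SE 0.84, adjusted p = 0.00248). Among matrix genes, Lum and Dcn, small proteoglycans, Postn and Col3a1 rose by log2 4.88, 4.28, 4.33 and 3.83, and Postn reached 215 ± 121 against 10.7 ± 0.341 CPM. Cardiac troponin I, Tnni3, reached 158 ± 12.2 against 8.71 ± 0.899 CPM (log2 4.19, SE 0.18, adjusted p = 0.00196), and Ryr2, the calcium release channel of heart muscle, rose by log2 3.88. Mbnl3, a splicing regulator, rose by log2 3.94.

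Among the largest falls, Lrmda, on chromosome 14 (22019712 to 23056085), fell by 4.80 on the log2 scale (SE 0.20), from 26.9 ± 2.75 to 0.957 ± 0.0691 CPM (SD, n = 2; adjusted p = 0.00196). The tight-junction gene Cldn9 fell from 53.2 ± 5.52 to 2.01 ± 0.384 CPM. Ptgds, Slc28a2, Nxf3, Col9a3, Adora2b, the connexin Gjb1, Pilra, Fxyd2 and Camkv fell by 4.32, 4.30, 4.07, 3.69, 3.68, 3.57, 3.50, 3.46 and 3.44 on the log2 scale. Cldn9 and Camkv are among the 10 leading genes of the control-rich cluster 1, and Col9a3 of cluster 8. C1qb, Cd52, Laptm5, Ryr2 and Pilra lie in chromosome regions that moved as blocks, described further on.

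Of 16140 genes tested with edgeR, 2522 rose and 1784 fell, and 6502 had an unadjusted p under 0.05. Both DUX-pulsed libraries lay beyond both controls for all 4306 called genes and for 67.6% of the genes tested. For a single gene chance gives 33.3%. Genes of a library are not independent, so that value is no yardstick for a share over all genes. The number called fell to 2708 without control replicate 1, to 2134 without control replicate 2, and to 2042 in cells with at least 1000 genes and at most 5% mitochondrial counts. The call of Fcer1g (adjusted p = 0.0476) was lost under 6 of its 16 alternatives, with adjusted p from 0.000216 to 0.18. Without genes of the shifted chromosome regions and chromosome Y, 1877 rose and 1425 fell.

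**Figure D2:**
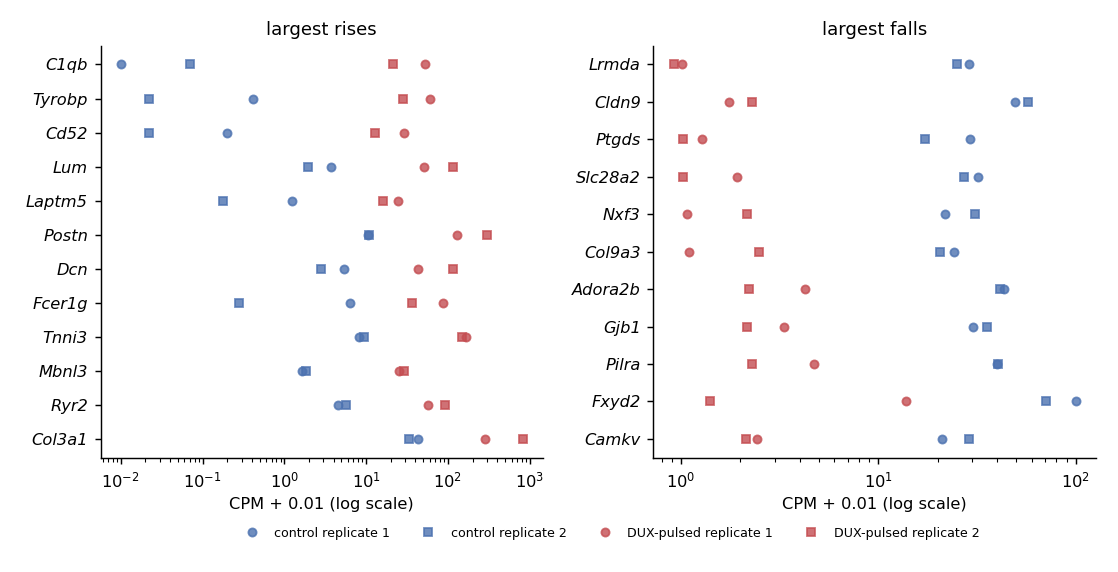
CPM per library (log axis, 0.01 added) of the 12 genes with the largest rise and 11 of the 12 with the largest fall. Circles and squares are replicates 1 and 2, blue for control and red for DUX-pulsed. Both DUX-pulsed libraries lie on the same side of both controls for each gene shown, which the rule for naming them required.

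Heart muscle genes rose together. All 16 cardiomyocyte markers tested rose (16 when adjusted over the list alone), with a median log2 fold change of 2.43. They were the sarcomere genes Myh6 (363 ± 50.4 against 50.9 ± 8.9 CPM; SD, n = 2), Tnni3, Ttn and Myl2, the atrial hormone Nppa and the transcription factors Tbx5 and Nkx2-5 among others. Ryr2 and Nppa lie in shifted regions with higher levels and Myl2 in a shifted region with lower levels in DUX-pulsed cells. The list passed camera (adjusted p = 7.83e-12; adjusted p = 0.537 with an estimated correlation). In the mesenchyme and fibroblast list 13 of 18 rose, 0 fell and 5 were not called (13 rose when adjusted over the list alone), led by Postn and Lum (camera adjusted p = 4.6e-06; adjusted p = 0.537 with an estimated correlation). The extracellular matrix list, which shares 9 members with others, had 11 of 23 higher and 0 lower (13 and 1 adjusted over the list alone). Its leading members were Vcan, at 396 ± 133 against 35.3 ± 1.1 CPM, and Nid1, at 59.3 ± 3.77 against 6.57 ± 2.37 CPM, both in the shifted part of chromosome 13 (camera adjusted p = 0.00102; adjusted p = 0.537 with an estimated correlation). The cardiomyocyte-like and mesenchyme-like shares of cells differed in the same direction, as given above. These classes were named from the same marker lists in the same cells, so the shares are not separate evidence.

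Blood and vessel genes were mostly higher. In the erythroid list 13 of 15 rose and 1 fell (13 and 1 adjusted over the list alone). The globins Hbb-y and Hbb-bt reached 2122 ± 819 against 330 ± 96.9 CPM and 16.4 ± 6.4 against 0.573 ± 0.187 CPM, while the carbonic anhydrase Car2 fell by 1.04 on the log2 scale (camera adjusted p = 0.000165; adjusted p = 0.538 with an estimated correlation). The erythroid list did not pass in cells with at least 1000 genes and at most 5% mitochondrial counts (adjusted p = 0.551; range with the preset correlation 1.36e-07 to 0.551). In the myeloid and megakaryocyte list 12 of 18 rose and 0 fell (12 adjusted over the list alone), led by the macrophage receptor Cx3cr1, at 14.8 ± 5.1 against 0.0809 ± 0.0403 CPM, and C1qb (camera adjusted p = 2.85e-06; adjusted p = 0.537 with an estimated correlation). In the endothelium list 8 of 15 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.00446; adjusted p = 0.558 with an estimated correlation). Emcn reached 10.3 ± 2.07 against 0.534 ± 0.343 CPM, and Kdr and Cdh5 rose by log2 1.81 and 1.93. The members that fell were Ramp2, from 289 ± 10.4 to 96.8 ± 4.99 CPM, and the VEGF receptor Flt1, which lies in the shifted part of chromosome 5 and was among the leading genes of the control-rich cluster 1.

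The visceral and definitive endoderm, primitive streak and primed epiblast lists passed downward. In the visceral and primitive endoderm list 12 of 20 fell and 1 rose (13 and 1 adjusted over the list alone). Ttr, the thyroxine carrier, fell from 6218 ± 41 to 1732 ± 141 CPM, and Cdx2, in the shifted part of chromosome 5, from 75.5 ± 3.74 to 27.3 ± 2.54 CPM, while Afp rose from 683 ± 88.6 to 1360 ± 119 CPM (camera adjusted p = 0.000165; adjusted p = 0.538 with an estimated correlation). In the definitive endoderm and gut list 6 of 15 fell and 1, Nkx2-1, rose (6 and 2 adjusted over the list alone). The protease inhibitor Spink1 fell from 6404 ± 31.3 to 807.9 ± 69 CPM and Car4 from 1011 ± 113 to 192 ± 30.2 CPM (camera adjusted p = 0.00328; adjusted p = 0.537 with an estimated correlation). In the primitive streak and nascent mesoderm list 6 of 12 fell and 0 rose (8 fell adjusted over the list alone), with Mixl1 at 0.0457 ± 0.0257 against 7.21 ± 2.39 CPM and Eomes at 2.14 ± 0.904 against 19.6 ± 5.54 CPM (camera adjusted p = 0.000165; adjusted p = 0.537 with an estimated correlation). In the primed epiblast list 5 of 10 fell and Dnmt3a rose (5 and 2 adjusted over the list alone). The DNA methyltransferase Dnmt3b fell from 105.4 ± 6.39 to 20.8 ± 0.244 CPM and Fgf5 by 3.40 on the log2 scale (camera adjusted p = 0.0235; adjusted p = 0.537 with an estimated correlation).

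In the pluripotency list 4 of 18 fell, 0 rose and 14 were not called (4 fell adjusted over the list alone). They were Tfcp2l1 (21.5 ± 1.66 against 64.5 ± 8.89 CPM), Tdh (44 ± 26.6 against 271.5 ± 6.59 CPM), Utf1 and Nanog (camera adjusted p = 0.0177; adjusted p = 0.558 with an estimated correlation). The list was not past the threshold without DUX-pulsed replicate 2 (adjusted p = 0.0718; range with the preset correlation 1.46e-05 to 0.0718). The list of 2-cell stage genes and DUX targets had 8 of 50 members in the table and 4 tested, of which Sp110 rose, from 0.0757 ± 0.0477 to 1.01 ± 0.619 CPM, and Arg2 fell, from 1.23 ± 0.255 to 0.473 ± 0.00791 CPM (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.945; adjusted p = 0.96 with an estimated correlation). Its median and camera pointed up and fry down, and camera pointed down without control replicate 1 (adjusted p = 0.977), DUX-pulsed replicate 1 (0.487) or DUX-pulsed replicate 2 (0.485), with a range of 0.485 to 0.977 under the preset correlation. Arg2 was not called without control replicate 1 (adjusted p = 0.0688) or control replicate 2 (0.212), with a range of 0.0187 to 0.212 over its alternatives.

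**Figure D3:**
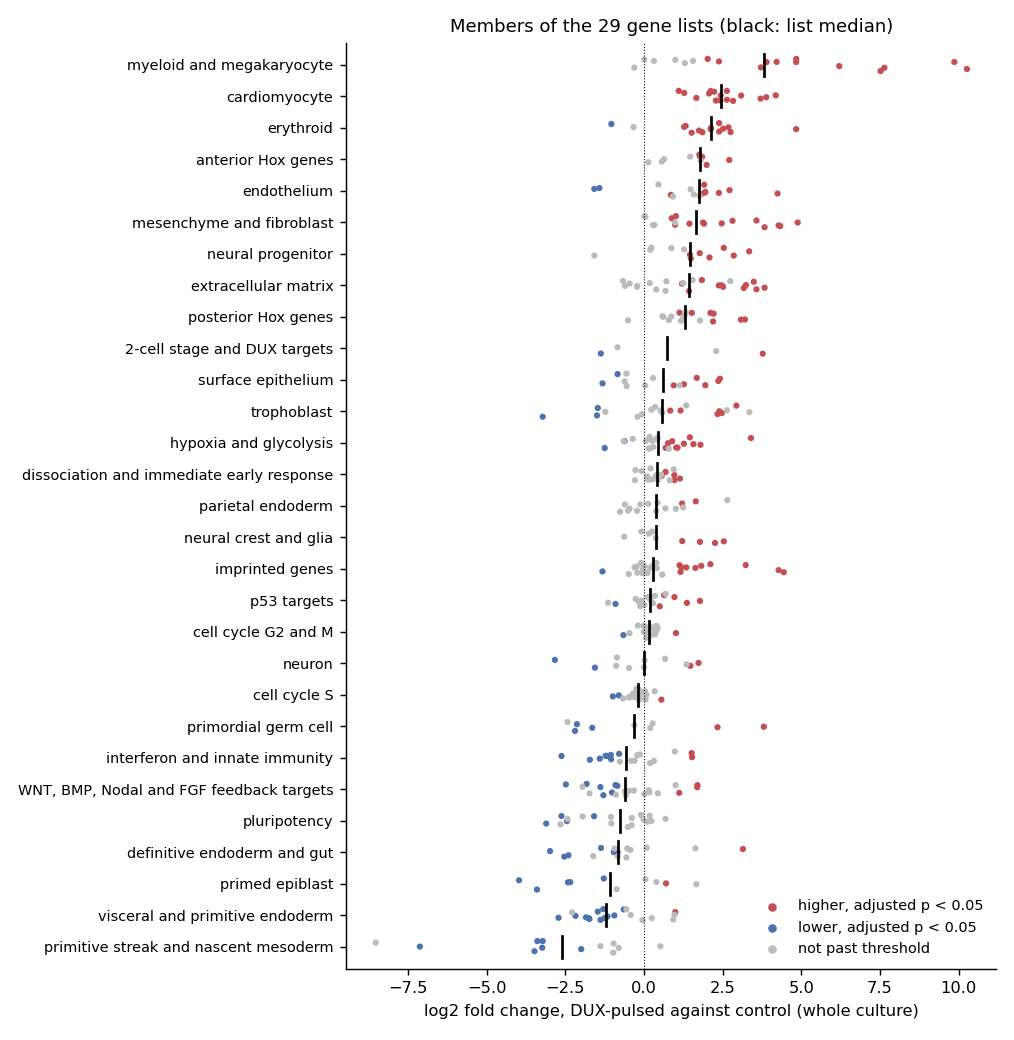
Log2 fold change, DUX-pulsed against control, of each tested member of the 29 gene lists (points) with the list median (black bar). Red and blue points passed an adjusted p of 0.05 upward and downward; grey points did not. All 16 cardiomyocyte markers lie to the right of 0, and 12 of 20 visceral and primitive endoderm markers passed to the left.

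Among neural and position genes, the neural progenitor list had 7 of 12 higher and 0 lower (8 and 1 adjusted over the list alone). Nes, an intermediate filament gene, reached 35.5 ± 2.94 against 8.39 ± 0.345 CPM and the growth factor Ptn, also a leading gene of mesenchyme-like cluster 4, 149.9 ± 39.5 against 20.8 ± 3.52 CPM (camera adjusted p = 0.00152; adjusted p = 0.537 with an estimated correlation). Of the anterior Hox genes 5 of 10 rose and 0 fell (6 adjusted over the list alone), with Hoxb2 at 8.75 ± 0.0832 against 2.55 ± 0.188 CPM and Hoxb4 at 3.59 ± 0.565 against 1.06 ± 0.16 CPM (camera adjusted p = 0.00446; adjusted p = 0.537 with an estimated correlation). Hoxb4 was not called in thinned cells (adjusted p = 0.0872; range 3.27e-05 to 0.0872). Of the posterior Hox genes 7 of 17 rose and 0 fell (9 adjusted over the list alone), with Hoxc6 at 7.92 ± 5.92 against 0.928 ± 0.126 CPM and Hoxd8 at 2.75 ± 0.777 against 0.63 ± 0.221 CPM (camera adjusted p = 0.00152; adjusted p = 0.537 with an estimated correlation). The neuron list had 2 of 11 higher, Isl1 (19 ± 1.06 against 6.83 ± 1.1 CPM, in the shifted part of chromosome 13) and Stmn2, and 2 lower, Nefm (3.25 ± 1.98 against 23.6 ± 4.27 CPM) and Stmn3. Its median of 0.00 and mean of -0.12 differed, and it did not pass (2 and 3 adjusted over the list alone; camera adjusted p = 0.703; adjusted p = 0.736 with an estimated correlation).

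Among signalling and metabolic groups, 10 of 24 hypoxia and glycolysis genes rose and 2 fell (10 and 2 adjusted over the list alone). Eno1, in the shifted part of chromosome 4, reached 1376 ± 106 against 463 ± 9.76 CPM and the collagen hydroxylase P4ha2 179.8 ± 20.9 against 51.9 ± 9.87 CPM, while the glucose transporter Slc2a3 fell by 1.25 on the log2 scale (camera adjusted p = 0.00481; adjusted p = 0.538 with an estimated correlation). Of the imprinted genes 10 of 28 rose and 1, Nap1l5, fell (10 and 1 adjusted over the list alone). Igf2 stood at 1.64 ± 0.246 against 0.074 ± 0.0157 CPM and Dlk1 at 49.5 ± 10.2 against 15.9 ± 0.911 CPM (camera adjusted p = 0.0184; adjusted p = 0.563 with an estimated correlation), and the list did not pass in cells with at least 1000 genes and at most 5% mitochondrial counts (adjusted p = 0.0647; range with the preset correlation 0.00207 to 0.0647). Of the WNT, BMP, Nodal and FGF feedback targets 7 of 22 fell and 3 rose (8 and 3 adjusted over the list alone), with Etv4 at 15.6 ± 1.01 against 38.1 ± 1.98 CPM, Dkk1 at 29.8 ± 4.83 against 77.9 ± 1.88 CPM, and Nodal lower by a log2 fold change of -2.48 (camera adjusted p = 0.046; adjusted p = 0.558 with an estimated correlation). That call was lost without DUX-pulsed replicate 1 (adjusted p = 0.191; range with the preset correlation 0.00848 to 0.191). Of the interferon and innate immunity genes 8 of 18 fell and 2 rose (9 and 2 adjusted over the list alone), with the ISG15 protease Usp18 at 3.35 ± 0.854 against 20.8 ± 0.393 CPM and H2-K1, an MHC class I gene, at 47.9 ± 0.743 against 98.9 ± 4.16 CPM (camera adjusted p = 0.0212; adjusted p = 0.538 with an estimated correlation). That call was lost without DUX-pulsed replicate 2 (adjusted p = 0.0935; range with the preset correlation 0.00177 to 0.0935).

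The dissociation and immediate early list had 5 of 20 higher and 0 lower (5 adjusted over the list alone), with Btg2 at 123.7 ± 4.99 against 63.2 ± 12.6 CPM and Ier3 at 72.5 ± 14.2 against 37.2 ± 2.34 CPM (camera adjusted p = 0.0177; adjusted p = 0.537 with an estimated correlation). Without control replicate 1 the list (adjusted p = 0.114; range with the preset correlation 0.00363 to 0.114) and Btg2 (0.0704; range 5.55e-05 to 0.0704) were not called, and without control replicate 2 Ier3 was not (0.0715; range 0.000113 to 0.0958). In the S phase list 2 of 22 fell, the repair enzyme Ung (37.4 ± 3.16 against 65.2 ± 0.706 CPM) and Chaf1b (35.4 ± 6.99 against 70.4 ± 9.2 CPM, in the shifted part of chromosome 16), and Rrm1 rose (2 lower and 0 higher adjusted over the list alone; camera adjusted p = 0.0312; adjusted p = 0.613 with an estimated correlation). This list was not called without control replicate 1 (adjusted p = 0.103), without DUX-pulsed replicate 2 (0.356), without genes of the shifted regions (0.13) or in cells with at least 1000 genes and at most 5% mitochondrial counts (0.146), with a range of 0.0128 to 0.356 under the preset correlation. Ung was not called without control replicate 1 (0.0608) or control replicate 2 (0.0556), nor Chaf1b without control replicate 1 (0.0608), with ranges of 3.86e-05 to 0.0608 and 8.04e-05 to 0.0608. In the G2 and M list 1 of 22 rose, Ccnb1 (120.8 ± 10.3 against 59.7 ± 2.51 CPM, in the shifted part of chromosome 13), and 1 fell, Aurka (54.3 ± 5.53 against 85.6 ± 1.63 CPM), with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.151; adjusted p = 0.736 with an estimated correlation). The list passed without DUX-pulsed replicate 2 (adjusted p = 0.0388) and in cells with at least 1000 genes and at most 5% mitochondrial counts (0.0291; range with the preset correlation 0.0291 to 0.684). Aurka was not called without control replicate 1 (0.117), control replicate 2 (0.139) or DUX-pulsed replicate 2 (0.069), with a range of 0.00125 to 0.139.

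The other lists were not called. In the trophoblast list 6 of 19 rose, among them Gata2 (12.4 ± 1.28 against 1.61 ± 0.0471 CPM) and Hand1 (111.8 ± 23.2 against 20.1 ± 4.11 CPM), and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.225; adjusted p = 0.672 with an estimated correlation). It passed without DUX-pulsed replicate 2 (adjusted p = 0.0213) and without genes of the shifted regions (0.0398), with a range of 0.0213 to 0.674 under the preset correlation. In the parietal endoderm list Lamc1 (155.9 ± 45.7 against 67.4 ± 5.55 CPM) and Snai1 (11.4 ± 3.31 against 3.65 ± 1.6 CPM) rose and 13 of 15 were not called (2 higher adjusted over the list alone; camera adjusted p = 0.712; adjusted p = 0.941 with an estimated correlation). It passed without DUX-pulsed replicate 2 (adjusted p = 0.00423; range with the preset correlation 0.00423 to 0.984), and pointed down without control replicate 2 (0.984) or DUX-pulsed replicate 1 (0.126). Snai1 was not called without control replicate 2 (0.0537; range 0.000163 to 0.0537). In the neural crest and glia list 4 of 9 rose, led by Ets1 (38.4 ± 0.0812 against 11.2 ± 3.51 CPM) and Tfap2a (2.69 ± 1.05 against 0.558 ± 0.0183 CPM, in the shifted part of chromosome 13), with 4 adjusted over the list alone (camera adjusted p = 0.0967; adjusted p = 0.558 with an estimated correlation). It passed without DUX-pulsed replicate 1 (0.0333) and with all deposited cells (0.0445), with a range of 0.0333 to 0.297 under the preset correlation. In the surface epithelium list 6 of 14 rose and 2 fell (7 and 5 adjusted over the list alone), with the keratin Krt14 at 2.37 ± 0.395 against 0.465 ± 0.271 CPM and Epcam at 318 ± 15.2 against 570.3 ± 88.4 CPM (camera adjusted p = 0.417; adjusted p = 0.617 with an estimated correlation). Epcam was not called without control replicate 2 (0.0979; range 5.84e-05 to 0.0979). In the primordial germ cell list 2 of 9 rose and 3 fell, with the same counts adjusted over the list alone, and Dnd1 stood at 1.96 ± 0.248 against 9.02 ± 2.61 CPM and Prdm1 at 7.44 ± 2.35 against 23.2 ± 3.63 CPM (camera adjusted p = 0.367; adjusted p = 0.704 with an estimated correlation). This list pointed up without control replicate 1 (0.977; range with the preset correlation 0.27 to 0.977). Of the p53 targets 5 of 20 rose and 1 fell (the same adjusted over the list alone), with Plk2 at 89 ± 7.62 against 34.6 ± 3.88 CPM in the shifted part of chromosome 13 and Btg2 as above (camera adjusted p = 0.214; adjusted p = 0.613 with an estimated correlation).

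Of the 29 lists, 12 passed camera upward and 8 downward. With an estimated correlation 0 passed and 0 had an unadjusted p under 0.05. With fry 0 passed, 14 had an unadjusted p under 0.05, and 28 had an unadjusted p under 0.05 for a change in either direction.

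The third comparison asked which genes differed within a class of cells. In the cardiomyocyte-like class 995 genes rose and 886 fell of 11368 tested with edgeR (3339 with an unadjusted p under 0.05). Most control cells of this class were in cluster 15, led by Tdgf1, Ankrd1 and Acta2 (3.34% of control and 1.33% of DUX-pulsed cells). Most DUX-pulsed cells of it were in clusters 6 and 16, led by Myl3, Tnni3, Myh7 and Myl2 (14.56% and 4.78% of DUX-pulsed cells). Within the class the homeobox genes Msx2 and Irx4 and the actin-bundling gene Espn rose by log2 3.40, 3.31 and 5.22. Espn reached 69.8 ± 22.4 against 1.75 ± 1.97 CPM (SD, n = 2; adjusted p = 2.31e-06). Espn lies in the shifted part of chromosome 4, and Msx2 and Irx4 in that of chromosome 13. Afp reached 68.3 ± 27.4 against 6.84 ± 1.67 CPM (log2 3.33, adjusted p = 1.28e-05), next to 1360 ± 119 CPM in the DUX-pulsed cultures as a whole. Its call was lost when Scrublet doublets were removed before clustering (log2 0.66, adjusted p = 0.203; range over alternatives 4.38e-54 to 0.203).

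Among the falls in cardiomyocyte-like cells, the smooth muscle myosin gene Myh11 had 105 and 196 UMIs in the controls and 0 in both DUX-pulsed libraries. On pooled counts without TMM scaling that was at least 312-fold lower, with the floor set at 3 counts over the DUX-pulsed group. Lrmda fell from 50.3 ± 7.65 to 0.91 ± 1.1 CPM (log2 -5.66, adjusted p = 1.59e-06), the neuropeptide gene Gal from 42.2 ± 10.6 to 1.67 ± 1.07 CPM, and Nxf3 and Trap1a by 4.88 and 4.84 on the log2 scale. Without genes of the shifted regions and chromosome Y, 593 genes rose and 695 fell. The class had 1142 calls with DESeq2, and 1112, 1142 and 1095 without control replicate 2, DUX-pulsed replicate 1 and DUX-pulsed replicate 2.

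In the mesenchyme- and fibroblast-like class 556 genes rose and 410 fell of 12097 tested (2734 with an unadjusted p under 0.05). Mbnl3 rose from 9.73 ± 2.55 to 75.6 ± 3.54 CPM (SD, n = 2; adjusted p = 0.000712) and Lum from 52.8 ± 12.2 to 338 ± 120 CPM. The vasoactive peptide gene Adm rose by log2 2.45, and Fam213b, in the shifted part of chromosome 4, by log2 2.42. Lrmda had the largest named fall, from 37.9 ± 0.705 to 0.626 ± 0.0314 CPM (log2 -5.88). The interferon-induced genes Rtp4, Usp18, Isg15 and Oas1a were the other named falls: Rtp4 from 39.6 ± 0.757 to 1.49 ± 0.165 CPM (adjusted p = 0.000125), Usp18 from 28.1 ± 0.405 to 1.66 ± 0.635 CPM, Isg15 from 70.7 ± 4.91 to 4.66 ± 1.89 CPM and Oas1a by 4.54 on the log2 scale. Oas1a lies in the shifted part of chromosome 5, which was lower in DUX-pulsed cells, and Isg15 in that of chromosome 4, which was higher. No gene list was tested within the class. Without genes of the shifted regions and chromosome Y, 177 genes rose and 250 fell, and 1889 genes were called with no filter on low counts.

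Of 10924 genes tested in both classes, 286 rose in both and 179 fell in both, where independent lists of the same lengths would share 40.3 and 24.2. Without genes of the shifted regions and chromosome Y, 56 of 9939 genes rose in both and 99 fell in both, where independent lists would share 7 and 11.4. The sums of both classes came from the same 4 libraries and were not independent. The difference between DUX-pulsed and control cells itself differed between the classes (class-by-group term) for 1137 of 12922 genes, with 732 higher in mesenchyme-like and 405 higher in cardiomyocyte-like cells and 2988 with an unadjusted p under 0.05. Without DUX-pulsed replicate 2 the number was 727. For Lrmda the term was small (log2 -0.20, adjusted p = 0.89).

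Fold changes were also ordered along the chromosomes, a step chosen after the data were seen. Of 247 bins of 10 Mb, 21 were shifted in the same direction in both classes, in 6 regions on 5 chromosomes (mm10). Chromosome 13 from 10 to 120 Mb was higher in DUX-pulsed cells, with medians of 0.96 and 0.92 (log2) over 392 genes in cardiomyocyte-like and mesenchyme-like cells. Chromosome 4 from 130 to 160 Mb (0.92 and 0.93, 235 genes) and chromosome 14 from 120 to 130 Mb (1.19 and 1.03, 12 genes) were also higher. Chromosome 5 from 120 to 150 Mb (-0.54 and -0.43, 267 genes), chromosome 14 from 100 to 110 Mb (-0.99 in both, 14 genes) and chromosome 16 from 80 to 100 Mb (-0.70 and -0.57, 61 genes) were lower. Shuffled gene positions gave at most 2 shifted bins in 1000 shuffles (permutation p = 0.001, the smallest they can give), and the replicates of either group gave 0. These regions and chromosome Y held 8.9% of the genes tested in the whole culture and 18.3% of its calls, and 27.4% and 39.2% of the calls in cardiomyocyte-like and mesenchyme-like cells. The shifts separate the same 2 groups of libraries as the DUX pulse. Any effects of the 2 on class shares or on genes elsewhere cannot be told apart. Leaving out genes of the regions does not change that. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d had 0 UMIs in the kept cells of either control. In the DUX-pulsed libraries Eif2s3y had 772 and 622 UMIs and Ddx3y 553 and 511. Uty had 12 and 9 UMIs in the controls and 236 and 235 in the DUX-pulsed libraries.

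**Figure D4:**
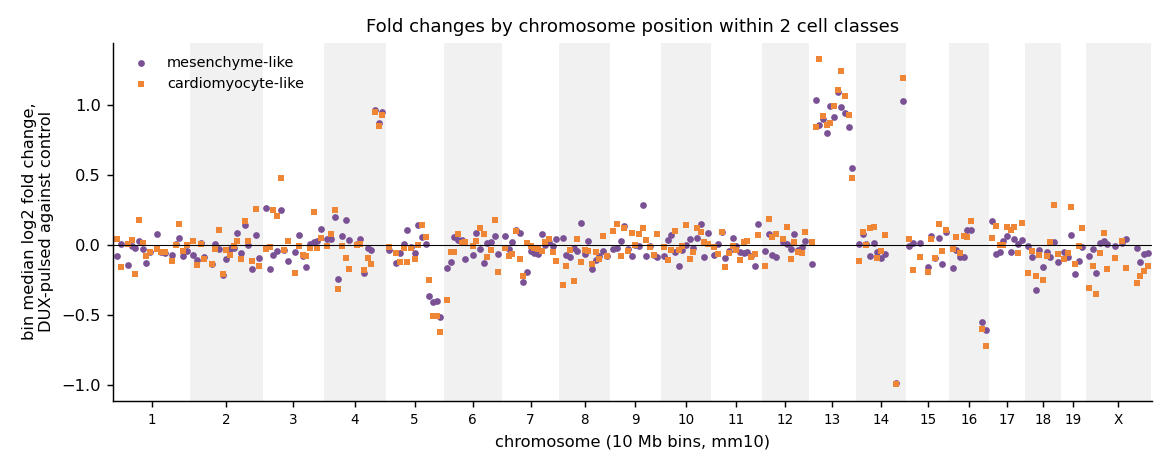
Median log2 fold change, DUX-pulsed against control, of genes in 10 Mb bins along each chromosome (mm10), in mesenchyme-like (purple) and cardiomyocyte-like cells (orange). On chromosome 13 the bins from 10 to 120 Mb lie between 0.478 and 1.331 and the bin before them at 0.022 and -0.132. The last 3 bins of chromosome 5 lie between -0.619 and -0.401.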

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

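The class-by-group term behind the values of this part was planned, and Tagln and Itm2a were singled out after their values were seen. The difference between DUX-pulsed and control cells differed between mesenchyme-like and cardiomyocyte-like cells for 1137 of 12922 genes tested with edgeR, which is why these results are listed here. The smooth muscle and cytoskeletal gene Tagln had the smallest p: it fell in cardiomyocyte-like cells (log2 -3.58) and did not pass in mesenchyme-like cells (0.48, adjusted p = 0.145), a difference of 4.03 (adjusted p = 1.54e-11). Itm2a differed the same way, by 2.84 (adjusted p = 4.85e-10). The cardiomyocyte-like class was made of different clusters in the 2 groups. Cluster 15, with Acta2 and Cnn1 among its leading genes, held 3.34% of control and 1.33% of DUX-pulsed cells, and clusters 6 and 16 held 0.74% and 0.45% against 14.56% and 4.78%. No technical or biological explanation was tested for these differences.

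Of the genes named within classes, 5 had effects that differed between the classes. Myh11, at 0 UMIs in DUX-pulsed cardiomyocyte-like cells, stood at 1.35 ± 1.76 CPM in DUX-pulsed and 1.28 ± 1.42 CPM in control mesenchyme-like cells (SD, n = 2), and the adjusted p of the difference was 0.000174. Afp rose by log2 3.33 in cardiomyocyte-like cells and did not pass in mesenchyme-like cells (0.83, adjusted p = 0.221), with an adjusted p of 0.0186 for the difference. The rise in cardiomyocyte-like cells was smaller and not called with Scrublet doublets removed (log2 0.66, adjusted p = 0.203), without the top 5% of Scrublet scores (0.79, adjusted p = 0.141) and when clustered without called genes (1.24, adjusted p = 0.053), with a range of 4.38e-54 to 0.203, and the difference between classes was not retested there. Gal fell in cardiomyocyte-like cells and was too low to be tested alone in mesenchyme-like cells (adjusted p of the difference 0.0187). Nxf3 fell in both, by 4.88 and 3.26 on the log2 scale (adjusted p of the difference 0.0421). Usp18 fell by 4.05 in mesenchyme-like cells and did not pass in cardiomyocyte-like cells (log2 -1.86, adjusted p = 0.0509), with an adjusted p of 0.0337 for the difference.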

How the results depend on the processing

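The fits without genes of the shifted regions, without cells under 5000 UMIs and without the top 5% of Scrublet scores, and the clustering without called genes as used within classes, were chosen after the results were seen. The 76 genes named from the whole culture kept their direction in all 1187 values and their call in 1156 of them. The 20 genes named within classes kept both in 299 of 302 values, and the other 3 belong to Afp in cardiomyocyte-like cells. For the 29 gene lists 281 of 348 values kept direction and call, 50 lost the call, 7 gained it and 10 pointed the other way.

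The number of genes called in the whole culture fell from 4306 to 2042 in cells with at least 1000 genes and at most 5% mitochondrial counts, and ran from 2134 to 4972 with each library left out in turn. In the strict cells Hbb-y (adjusted p = 0.148; range 6.02e-16 to 0.148) and Krt14 (0.122; range 0.000193 to 0.122) lost their calls, as did Sp110 (0.074; range 0.000182 to 0.074), Hoxc6 (0.0652; range 7.34e-08 to 0.0652), Isl1 (0.06; range 9.18e-09 to 0.06), Hoxb2 (0.0555; range 2.8e-10 to 0.0555) and Tfap2a (0.0535; range 2.76e-05 to 0.0535). Fcer1g (0.18), Ier3 (0.0958), Arg2 (0.0806), Epcam (0.0666), Aurka (0.0614) and Btg2 (0.0521) also lost them there, with their ranges given in the report. Rises were smaller in the strict cells for Hbb-y (log2 0.958 against 2.68), Isl1 (0.665 against 1.47) and Hoxb2 (0.801 against 1.78). The strict cells were 644 and 523 in the controls and 1320 and 694 in the DUX-pulsed libraries. In the cardiomyocyte-like class DESeq2 called 1142 genes against 1881, and in the mesenchyme-like class no count filter gave 1889 and leaving out genes of the shifted regions 427 against 966. With each library left out the numbers ran from 1095 to 1407 and from 657 to 831, and for the class-by-group term from 727 to 1308. A group left with 1 library was assumed to vary like the other. Fewer genes were tested without the shifted regions, but calls were also lost among the genes that stayed. Of the 966 mesenchyme-like calls 587 lay outside the regions and chromosome Y, and the refit called 427. In the cardiomyocyte-like class 1366 calls lay outside and the refit called 1288, and in the whole culture 3516 and 3302. The cause of these losses, and of the changes under the other settings, was not tested.

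With an estimated correlation or with fry in place of camera 0 of 29 lists passed, with 0 and 14 at an unadjusted p under 0.05. The list of 2-cell stage genes and DUX targets, with 4 genes, pointed down with fry (adjusted p = 0.761), with all deposited cells (0.565) and in the strict cells (0.733), and ran from 0.485 to 0.977 with each library left out. The neuron list pointed up in the strict cells (0.916). With each library left out the primordial germ cell list ran from 0.27 to 0.977 and the parietal endoderm list from 0.00423 to 0.984, with changes of direction in both. The cause was not tested.

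Of the shares of the 8 named classes, 5 passed, and 2 did with TMM on the class counts, 1 in the strict cells and 3 at Leiden resolution 0.5, where no visceral endoderm-like or trophoblast-like cluster met the naming rule. With TMM the cardiomyocyte-like, erythroid-like and mesenchyme-like rises were 0.846, 0.349 and 0.638 (log2) and did not pass. In the strict cells the cardiomyocyte-like, erythroid-like and trophoblast-like rises were 0.883, 0.226 and 4.08 and did not pass, and no cluster was named mesenchyme-like. Without the top 5% of Scrublet scores endothelium-like, myeloid-like and parietal endoderm-like cells passed, at 1.76, 2.31 and 2.82. No trophoblast-like cluster was named with 30 neighbours or without the top 5% of Scrublet scores. The cause was not tested.

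With each library left out, 2 to 7 named classes passed. The log2 changes ran from 2.01 to 2.39 for cardiomyocyte-like, 1.69 to 2.31 for mesenchyme-like, 1.41 to 2.01 for erythroid-like, 1.18 to 2.89 for endothelium-like, 1.53 to 3.45 for myeloid-like and 0.818 to 4.35 for parietal endoderm-like cells. The visceral endoderm-like fall passed in all 15 alternatives in which that class was named.

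With the replicate number as a replicate block 7184 genes were called in the whole culture, 3921 in cardiomyocyte-like and 2796 in mesenchyme-like cells, and all 8 named classes passed, with endothelium-like, myeloid-like and parietal endoderm-like cells at 1.90, 2.30 and 2.61. The labels do not say that equal numbers shared a batch, and deviations of genes from their group means had a correlation of 0.35 between libraries of the same number.

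Cell numbers limit the rarest groups: DUX-pulsed libraries held 3 visceral endoderm-like cells each and controls 1 and 0 trophoblast-like cells. The whole-culture test called 47% of simulated 2-fold changes, which were planted in genes with counts well above the filter. It called 3414 genes with cells thinned to 5000 UMIs. The tests of genes and shares ran on counts, and no other offset was tried for the log CPM of camera and fry.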

Other observations

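The bins along chromosomes, the per-cell shares and all tests of this part were chosen after the results were seen, except the tests with thinned cells and with Y-linked transcripts by class, whose expected outcomes were written before. Most control cells lay in clusters that took no name. Cluster 3, led by the cell cycle genes Cenpf, Kif23 and Kif22, held 12.06% ± 2.37 (SD, n = 2) of control and 1.05% ± 0.03 of DUX-pulsed cells. Cluster 12, led by Onecut2, Tff3 and Anpep, held 5.84% ± 2.35 against 0.27% ± 0.04. Cluster 14, with Dppa5a, Sox2 and Foxe1 among its leading genes, held 1.96% ± 1.28 against 3.68% ± 1.65.

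Genes of 6 chromosome regions moved together in cardiomyocyte-like and mesenchyme-like cells. The direction was the same in endothelium-like, myeloid-like and parietal endoderm-like cells for 21 of 21 bins and in erythroid-like cells for 19 of 19. In size the parietal endoderm-like class stood apart, with medians of 0.266 (log2) for the chromosome 4 region and -0.09 for the chromosome 5 region, against 0.926 and -0.531 in endothelium-like cells. Chance placement was argued against by shuffled gene positions (permutation p = 0.001, the smallest 1000 shuffles can give). A different makeup of cell types was argued against for the chromosome 13 region alone, whose median was at least 0.89 (log2) in each of those 4 other classes. Left out were trophoblast-like cells, with 1 control cell, and visceral endoderm-like cells, with 3 in each DUX-pulsed library. Their medians for the regions of chromosomes 4, 5 and 13 were 0.192, -0.056 and 0.201 in the former and 0.841, -0.434 and 0.943 in the latter. Depth was argued against by the median of 0.941 for the chromosome 13 region in the whole culture with cells thinned.

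Across cells of at least 10000 UMIs the chromosome 13 share of counts had medians of 2.13% and 2.11% in the controls and 4.02% and 3.95% in the DUX-pulsed libraries. The 5th percentile of either DUX-pulsed library lay at least 0.764 percentage points above the 95th percentile of either control. A different number of copies of the chromosome 13 region in the cells behind the 2 groups is a candidate explanation. The other 5 regions were not put to this test. For the chromosome 5 region the share was spread widely over control cells. In unnamed control cells of at least 10000 UMIs its medians were 3.418% and 3.343% and its 25th percentiles 2.638% and 2.566%. Unnamed DUX-pulsed cells had medians of 2.282% and 2.218% and 75th percentiles of 2.396% and 2.319%. Whether all control cells differed from DUX-pulsed cells in that region was not tested. DNA was not measured, and the DUX pulse itself as the cause is confounded with the group and stays open. Relative to all genes of a library, the median level of chromosome 13 genes (log2) was -0.763 and -0.891 in control and 0.102 and 0.038 in DUX-pulsed cardiomyocyte-like cells. In mesenchyme-like cells it was -0.62 and -0.776 against 0.203 and 0.078. The other chromosomes lay between -0.254 and 0.232 in all libraries of both classes, so on chromosome 13 the controls stood apart from the other chromosomes and the DUX-pulsed libraries did not. In control replicate 1 the 52 parietal endoderm-like cells had a median share of 2.849% for the end of chromosome 4, against 2.876% in DUX-pulsed replicate 1, and of 1.816% against 3.444% for chromosome 13.

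Y-linked transcripts were found in 19.001% and 25.149% of DUX-pulsed cells and in 0.507% and 0.427% of control cells of at least 10000 UMIs. The control UMIs were all from Uty. Low expression in all cells was argued against by the share expected from an even spread over cells by depth, 53.1% and 69.7%, which lay at least 34.1 percentage points higher. Classes that differ in Y-linked expression were argued against within mesenchyme-like cells, where the share reached at most 37.9% of the evenly spread one. Cells of a control-like culture mixed in were argued against by the chromosome 13 share, whose median differed by at most 0.018 percentage points between cells with and without a Y-linked UMI. That neither median lay near the controls already followed from the percentiles above, so this is not separate evidence. Loss of chromosome Y from part of the cells may account for this and was not tested, and the DUX pulse is confounded with the group.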
